A study of Arabidopsis thaliana with 18 samples.

How the data were processed

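The 18 libraries were made from total RNA, extracted with TRIzol, of 4-day-old Arabidopsis seedlings grown on half-strength Murashige and Skoog medium, with a stranded Illumina mRNA kit. The groups were dark-grown wild type (n = 6), dark-grown cry2-1 (n = 3), wild type and cry2-1 after 30 min of blue light (n = 3 each) and a dark-grown quadruple mutant in FKD1, FL1, FL2 and FL3 (labelled flΔ4, written fl4 here, n = 3). The submitters' notes name fastp for read trimming, HISAT2 for alignment to TAIR10 and StringTie for abundance. Their versions and settings are not given in the sources used here. The authors deposited 1 table per library with TPM for 32833 genes.

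Raw reads and read counts were not used here. TPM keep no read totals, so depth per library and the counting error of single genes are unknown, and precision was judged from the spread of replicates alone. TPM are shares of a library, so a change in a few abundant RNAs moves all others. Values were matched by locus to the TAIR10.1 annotation (32548 loci matched, and the other 285 were loci of the chloroplast and mitochondrial genomes). Because its build differs in name from that of the notes, only chromosome, gene order and overlap were taken from it. The TPM of 5 rRNA loci were followed.

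Groups, comparisons, alternatives and the 24 gene lists were fixed before the data were examined. That plan assumed read counts, so its fallback for normalized values was used: linear models in limma 3.58.1 (R 4.3.3, jsonlite 2.0.0) on log2(TPM + 1) with a mean-variance trend and robust moderation. Genes with a mean of at least 1 TPM over the libraries of a fit were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Changes are given with the standard error of the model, and TPM with the standard deviation. For genes near 0 TPM the added 1 shrinks the fold change.

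The labels set wild type against cry2 in darkness and blue light, and wild type against fl4 in darkness. One fit of 12 libraries (WT_dark 1-3, cry2_dark, WT_blue and cry2_blue) gave the light response in each genotype, the genotype effect in each condition and their interaction. One fit of 6 libraries set fl4_dark against WT_dark 4-6, and another set the dark wild-type libraries against each other. Which dark libraries belong to which mutant is not stated. The assignment was read from the numbering of the titles. As planned, the light response of wild type, the cry2 effect in darkness and the fl4 effect were repeated against the other dark set, and these and the interaction against all 6 dark libraries. After the values were seen, WT_dark 4-6 were also used in the interaction, and genes called in the same direction against both sets were counted.

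The lists (448 entries, written from general knowledge of the genes) were genotype targets; other photoreceptors and light signalling hubs; mitosis and G2/M; S phase and DNA replication; CDK inhibitors; early light-induced regulators; flavonoid and anthocyanin synthesis; light harvesting and Rubisco; chlorophyll synthesis; PIF-induced growth genes; auxin response; auxin transport and synthesis; expansins and xyloglucan enzymes; circadian clock; touch, wounding and rapid stress; salicylate and pathogen response; sugar starvation and darkness; abscisic acid and dehydration; ethylene response; ribosome biogenesis; root tissue markers; shoot apex and stomatal lineage markers; vascular tissue markers; and seed reserves. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, each adjusted over the lists of a comparison. Counts of members are from the adjustment over all genes. A further adjustment over the list alone is given beside them where it differs. The size of the light response was compared between genotypes as the median interaction of genes called and changed at least 2-fold in the mean light effect of wild type and cry2, with fry as the set test.

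Genes named in the text were the targeted genes, the neighbours of CRY2 within 20 kb, up to 6 higher and 6 lower genes per comparison with the smallest p among those called, changed at least 2-fold, with a mean of at least 2 TPM and no overlap between libraries of the groups, and up to 4 genes per list. With 3 libraries against 3, such separation arises by chance in 10% of unchanged genes. Genes named for holding against both dark sets were chosen after the values were seen. Where a group was listed at 0, TPM are given in place of a fold change. Reads of near-identical copies (LHCB1, RBCS, histone H3, SAUR19 to SAUR24, BGLU34 and BGLU35, rRNA) may be shared between loci.

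Shared calls were tested with Fisher's exact test. The mutant effects in darkness share no libraries, so their correlation was computed across genes without a shared control. The pipeline was tested on simulated data made from these libraries, with 100 genes changed 2-fold and 100 changed 4-fold in each run. At 2-fold, 77.0% of them were recovered for the light response, 75.0% for cry2 in darkness, 41.0% for the interaction and 34.0% for fl4, and 4.40 to 6.72% of calls were unchanged genes. At 4-fold, 97.0%, 97.0%, 87.0% and 77.0% were recovered. Each gene was drawn independently, with no shift shared by whole libraries, so these error rates may not hold for the real comparisons.

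Alternatives were no filter, a filter of at least 5 TPM in 3 libraries, a pseudocount of 0.1, a 2-fold minimum, organelle loci left out, rRNA and organelle loci left out, each library scaled to its median gene, genes overlapping another gene left out, the replicate number as a block, fits of the compared groups only, other dark wild-type sets, and each library left out in turn. The count-based normalization, tool and filters in the plan were not run because the values are TPM. Overlaps were counted with Python 3.11.15, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.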

Results

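Transcript abundance was measured by sequencing of stranded mRNA libraries from 4-day-old Arabidopsis thaliana seedlings (18 libraries in 5 groups). Wild-type Col-0 seedlings kept in darkness made up 6 libraries, WT_dark 1-6. The other groups held 3 libraries each: dark-grown cry2-1 mutants, which lack the blue-light receptor cryptochrome 2 (cry2_dark), wild type and cry2-1 moved from darkness to blue light of 30 µmol per square metre and second for 30 min (WT_blue and cry2_blue), and a dark-grown quadruple mutant in FKD1, FL1, FL2 and FL3, labelled flΔ4 and written fl4 here (fl4_dark). FKD1 and its relatives, the FORKED-LIKE genes, act in leaf vein patterning. The deposited values were TPM, the length-scaled share of each gene in a library, for 32833 genes per library and summed to 997143 to 998279. The sequencing depth is unknown, because TPM keep none of the read totals. Between 18493 and 19645 genes reached 1 TPM per library.

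The dark wild-type libraries fell into 2 sets, and WT_dark 4-6 were closer to the blue-light libraries than to WT_dark 1-3. Library names in the file headers begin with Da or Db for WT_dark 1-3 and cry2_dark, with M for both blue-light groups, and with D for WT_dark 4-6 and fl4_dark. No label says what these prefixes stand for. Correlations of log2 values across genes were 0.951 to 0.961 between WT_dark 1-3 and cry2_dark and 0.881 to 0.890 between WT_dark 1-3 and 4-6. WT_blue correlated with WT_dark 4-6 at 0.897 to 0.945 and with WT_dark 1-3 at 0.828 to 0.838. The first principal component held 49.5% of the variance of 19927 genes and the second 14.1%. Ribosomal RNA loci took 56392 to 65586 TPM in WT_dark 1-3, 12231 to 15977 TPM in cry2_dark and 6550 to 7907 TPM in WT_dark 4-6. In fl4_dark 1, 2 and 3 they took 31348, 15784 and 11755 TPM. The 18S rRNA locus AT2G01010 was listed at 16491 to 19578 TPM in WT_dark 1-3, at 2420 to 3562 TPM in cry2_dark and at no more than 1.06 TPM in the other libraries. The 5.8S locus AT3G41979 went the other way, at 0.0 TPM in WT_dark 1-3, 1479 to 2436 TPM in WT_dark 4-6 and 3978 to 11002 TPM in fl4_dark. The summed rRNA loci therefore differ in make-up between the sets. Chloroplast and mitochondrial loci took 34290.0 to 36382 TPM in WT_dark 1-3 and 2076 to 2801 TPM in WT_dark 4-6.

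**Figure D1:**
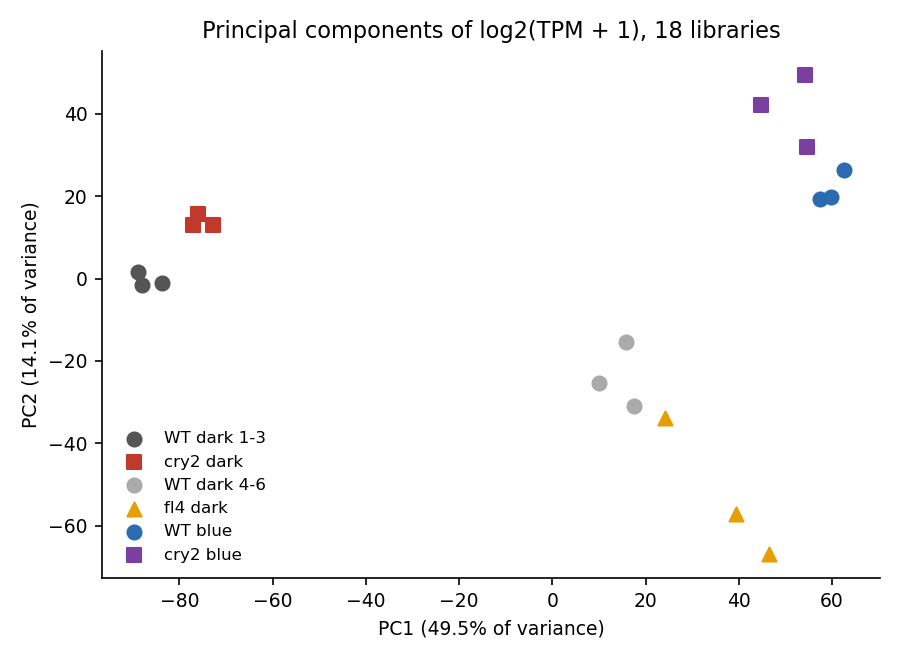
Scores of the 18 libraries on the first (49.5% of variance) and second (14.1%) principal components of log2(TPM + 1), with 1 point per library coloured by group. WT_dark 1-3 and WT_dark 4-6 stand apart although they share genotype and condition.

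To check the genotypes, the targeted genes were read in each library. CRY2 (AT1G04400, chromosome 1) was listed at 99.8, 110 and 106 TPM in WT_dark 1-3, at 0 in all 3 cry2_dark libraries and at 0.03, 0.06 and 0.03 TPM in cry2_blue, against 89.6, 90.6 and 73.3 TPM in WT_blue. The neighbouring genes AT1G04410, which encodes the cytosolic malate dehydrogenase c-NAD-MDH1, and AT1G04420 were also missing from cry2-1. AT1G04410 was listed at 767.75 to 831.5 TPM in WT_dark 1-3, at 0 in cry2_dark and at 0.19 to 0.22 TPM in cry2_blue. AT1G04420 was listed at 59.8 to 63.6 TPM in WT_dark 1-3 and at 0 in cry2_dark. The flanking genes AT1G04390 (2.67 to 3.77 TPM) and AT1G04430 (89.1 to 101 TPM) were present in cry2_dark. Because AT1G04410 and AT1G04420 were missing together with CRY2, no difference between cry2-1 and wild type below can be assigned to CRY2 alone. CRY1, the related receptor, was at 43.6 to 49.3 TPM in cry2_dark and 45.9 to 47.8 TPM in WT_dark 1-3.

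**Figure D2:**
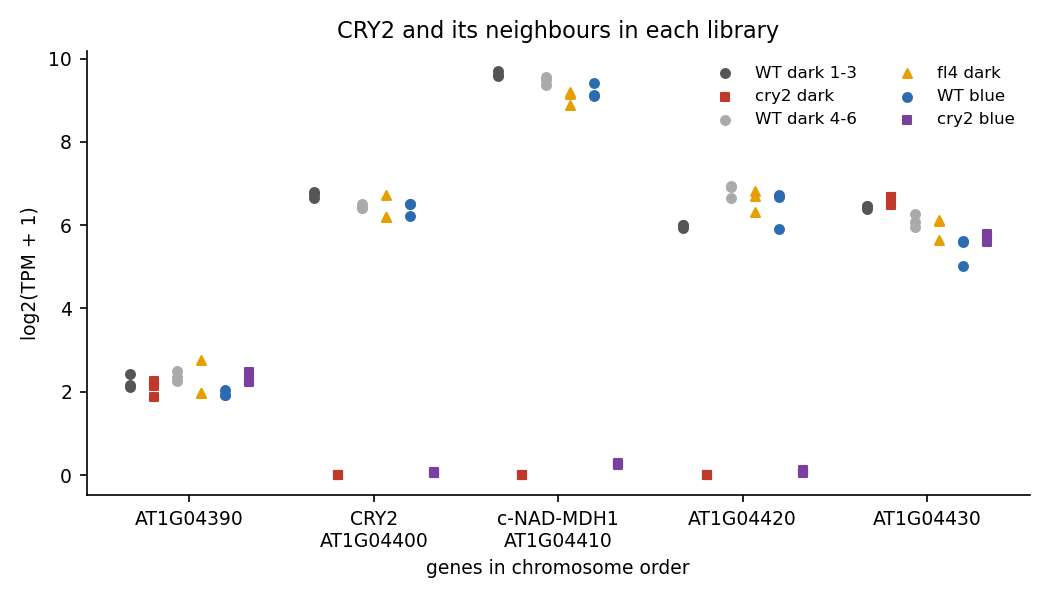
Log2(TPM + 1) of CRY2 and its neighbours on chromosome 1, with 1 point per library. AT1G04400, AT1G04410 and AT1G04420 are at or near 0 in the cry2 libraries, while AT1G04390 and AT1G04430 are present in all groups.

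Of the 4 genes targeted in fl4, only FL1 was lower against both dark sets. FL1 (AT5G43870) was listed at 0.36, 0.13 and 0.37 TPM in fl4_dark and at 2.81, 3.58 and 4.62 TPM in WT_dark 4-6, a log2 change of -1.85 ± 0.25 (SE, n = 3 and 3, adjusted p = 0.0378). Its call ended without fl4_dark 1, fl4_dark 2, WT_dark 5 or WT_dark 6 (-1.89, -1.76, -1.85 and -1.70), while against WT_dark 1-3 the change was -2.44 ± 0.21 (adjusted p = 3.31e-05). FKD1 (4.06, 3.70 and 5.76 TPM in fl4_dark against 5.67, 8.76 and 5.67), FL2 (4.98, 4.00 and 5.81 against 4.88, 4.97 and 5.13) and FL3 (7.16, 9.88 and 13.6 against 9.84, 7.95 and 9.63) did not pass the test. Against WT_dark 1-3 (16.5, 19.3 and 17.8 TPM) FL3 was lower (-0.79, adjusted p = 0.0120). Transcript levels alone do not show whether an insertion allele makes a working protein.

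Light-signalling, clock, growth and auxin genes differed between wild-type seedlings after 30 min of blue light and dark seedlings. The B-box genes BBX32, BBX31 and BBX30, which encode regulators of light signalling, rose together with the plastid sigma factor gene SIG5 and the clock genes PRR9, CCA1 and RVE1. The auxin-induced SAUR19, SAUR20, SAUR22 and SAUR24, linked to hypocotyl elongation, fell with expansin genes and PIF-induced growth genes. These statements rest on the genes called in the same direction against WT_dark 1-3 and against WT_dark 4-6, a restriction chosen after the data were seen. Of 19731 genes tested both ways, 4250 were called in the same direction (1474 higher and 2776 lower in blue light) and 224 in opposite directions. Both comparisons share the WT_blue libraries, which favours calls in the same direction, and no expected number was computed. Of the calls made both ways in the same direction, 677 higher and 298 lower genes were changed at least 2-fold.

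BBX32 (AT3G21150) was at 0.05 ± 0.06 TPM (SD, n = 3) in WT_dark 1-3, 0.34 ± 0.55 TPM in WT_dark 4-6 and 112 ± 23.8 TPM in WT_blue. On the log2(TPM + 1) scale used for all changes below, its increase was 6.72 ± 0.15 (SE, adjusted p = 5.78e-12) against the first dark set and 6.45 ± 0.24 (adjusted p = 7.47e-08) against the second. In the same order, the increases were 5.16 and 4.58 for BBX30 (AT4G15248), 4.05 and 3.85 for BBX31, 4.75 and 5.03 for PRR9 (AT2G46790) and 3.91 and 2.53 for PDX1L4 (AT2G38210), a member of the vitamin B6 synthase family. SIG5 (AT5G24120) increased by 5.09 against the first set and was called against the second. ABCI21 (AT5G44110), an ABC protein gene, increased by 3.97 and 3.34, and HBP1 (AT1G17100), a heme-binding protein gene, by 3.63 and 2.68. HSFA2, a heat stress transcription factor gene, increased by 4.91 and 4.26, and the brassinosteroid glucosyltransferase gene DOGT1 by 4.44 and 4.35. Among the genes that fell, the B-box gene BBX23 changed by -2.89 ± 0.15 and -3.42 ± 0.16, the growth-regulating factor gene GRF7 by -3.64 and -3.15 and the homeobox gene HAT2 by -1.80 and -1.72.

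Early light-induced regulators rose in wild type (24 rose and 1 fell of 26 tested, median 2.83, camera adjusted p = 6.81e-14), and 22 rose and 1 fell against both dark sets. The circadian clock list rose as well (24 rose and 1 fell of 28, median 1.94, adjusted p = 5.08e-12; 20 rose and 1 fell against both sets). CCA1, a morning-phased MYB gene, increased by 3.43 and 2.60, and LNK3, a clock coactivator gene, by 3.06 and 2.36. Expansins and xyloglucan enzymes, which loosen cell walls, fell (2 rose and 17 fell of 23, 2 and 19 adjusted over the list alone, median -1.02, adjusted p = 3.52e-05; 1 rose and 12 fell against both sets). EXPA8 changed by -2.72 and -1.60, EXPB1 by -2.72 and -1.55 and XTH4 by -1.63 and -0.72. These 3 lists also passed with an estimated correlation against WT_dark 1-3 (adjusted p = 0.0279, 0.0450 and 0.0279), unlike those below. Against WT_dark 4-6 they passed with the preset correlation (adjusted p = 3.54e-24, 9.89e-20 and 0.0087) but not with an estimated correlation (adjusted p = 0.0701, 0.0701 and 0.2848).

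PIF-induced growth genes fell (2 rose and 18 fell of 21, median -2.10, adjusted p = 5.74e-06, adjusted p = 0.1447 with an estimated correlation), as did auxin response genes (1 rose and 22 fell of 27, median -1.51, adjusted p = 1.58e-07, adjusted p = 0.1587 with an estimated correlation). Against both dark sets 2 rose and 17 fell in the first list and 19 of 26 fell in the second. IAA19, an auxin-responsive repressor gene, changed by -2.57 and -1.73, and PRE1, a growth-promoting helix-loop-helix gene, by -3.11 and -1.99. SAUR20 changed by -2.07 ± 0.09 and -2.12 ± 0.13 and SAUR24 by -2.61 and -2.66, though reads of the SAUR19 to SAUR24 copies may be shared. All 14 auxin transport and synthesis genes fell (median -1.32, adjusted p = 1.20e-06, adjusted p = 0.1763 with an estimated correlation), 11 of them against both sets, including the influx carrier gene AUX1 (-2.33 and -1.38) and ABCB19 (-2.18 and -1.11). Touch, wounding and rapid stress genes rose (14 rose and 1 fell of 20, median 1.99, adjusted p = 1.71e-05, adjusted p = 0.3573 with an estimated correlation; 14 rose against both sets). WRKY33, a defence regulator gene, increased by 2.98 and 2.91, and CBF2, a cold response factor gene, by 1.90 and 1.62.

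Light harvesting and Rubisco genes rose (20 of 22, none fell, median 1.54, adjusted p = 4.70e-09, adjusted p = 0.2140 with an estimated correlation), but 8 rose against both sets. LHCA1 increased by 2.99 and 1.32 and LHCB2.2 by 2.89 and 1.48. Chlorophyll synthesis genes rose against WT_dark 1-3 only (11 rose and 2 fell of 15, median 0.64, adjusted p = 0.0034, adjusted p = 0.4519 with an estimated correlation; median -0.17, adjusted p = 0.8969 against WT_dark 4-6), with 3 rising and 2 falling against both sets. Those rising included HEMA1, the first committed enzyme gene (1.57 and 0.75). Flavonoid genes rose (7 of 10, adjusted p = 0.0049, adjusted p = 0.3900 with an estimated correlation; 3 against both sets), including F3H (3.47 and 1.75). Mitotic genes fell (3 rose and 19 fell of 34, median -0.52, adjusted p = 0.0085, adjusted p = 0.4519 with an estimated correlation; 11 fell against both sets), including the kinase gene CDKB2;1 (-1.38 and -0.53) and the cytokinesis gene KNOLLE (-1.17 and -0.69). Of 32 S phase genes 5 rose and 12 fell (5 and 11 adjusted over the list alone, median -0.25, adjusted p = 0.2312) against WT_dark 1-3. Against WT_dark 4-6, 22 fell and 0 rose (median -0.50, adjusted p = 3.98e-06, adjusted p = 0.2548 with an estimated correlation), and 11 fell against both sets, including the replication clamp gene PCNA1 (-0.78 and -0.88).

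Root markers (0 rose and 9 fell of 11, median -1.28, adjusted p = 5.01e-04, adjusted p = 0.0796 with an estimated correlation) and vascular markers (0 rose and 12 fell of 15, median -1.43, adjusted p = 5.01e-04, adjusted p = 0.3501 with an estimated correlation) fell against WT_dark 1-3. Against both sets 3 of 10 and 4 of 15 fell. Ribosome biogenesis genes (6 of 8 fell, median -0.55, adjusted p = 0.0317, adjusted p = 0.4519 with an estimated correlation) lost their call without WT_dark 3 (adjusted p = 0.0549), and all 6 genes also fell against the second set. The nucleolin gene NUC1 changed by -1.02 and -0.70. Sugar starvation and darkness genes (2 rose and 10 fell of 18, median -0.36, adjusted p = 0.0468, adjusted p = 0.4730 with an estimated correlation) lost their call without WT_blue 2, WT_blue 3 or WT_dark 2 (adjusted p = 0.0711, 0.0607 and 0.0867), and 2 rose and 2 fell against both sets.

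The other lists did not pass as sets against WT_dark 1-3. Abscisic acid genes split there (6 rose and 3 fell of 12, 7 and 3 adjusted over the list alone, adjusted p = 0.2347) but rose against WT_dark 4-6 (7 rose and 1 fell, median 0.77, adjusted p = 1.03e-04, adjusted p = 0.0701 with an estimated correlation). Against WT_dark 1-3 there was also a split in ethylene response genes (2 rose and 3 fell of 11, adjusted p = 0.4490), salicylate and pathogen genes (3 and 2 of 6, adjusted p = 0.4521), photoreceptors and light signalling hubs (4 and 8 of 20, adjusted p = 0.7906) and shoot apex and stomatal markers (2 and 5 of 9, adjusted p = 0.1557). CDK inhibitor genes were higher in 5 of 10 (median 0.42, adjusted p = 0.0516) but in none against both sets. The photoreceptor genes PHYA (-1.78 and -1.16) and PHOT1 (-2.21 and -1.45) fell against both sets. Among the genotype targets 3 of 5 fell (adjusted p = 0.2926), and the change of CRY2 (-0.32, adjusted p = 0.0224) ended without WT_blue 3, WT_dark 2 or WT_dark 3 (-0.22, -0.29 and -0.31) and was -0.03 against WT_dark 4-6. Only 2 seed reserve genes were tested, too few for a set test, and EM6 (0.90, adjusted p = 0.0274) lost its call without WT_blue 2, WT_dark 1 or WT_dark 3 (0.63, 0.78 and 0.86).

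**Figure D3:**
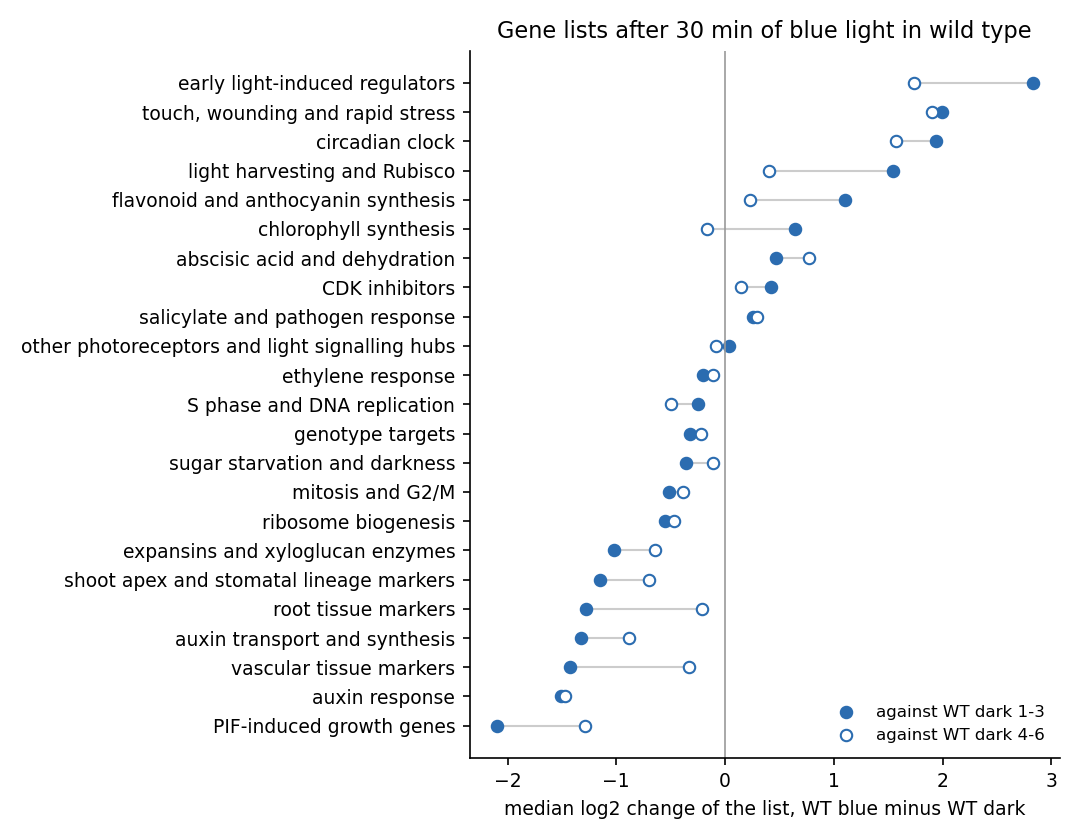
Median log2 change of each gene list in wild type after 30 min of blue light, with filled points against WT_dark 1-3 and open points against WT_dark 4-6. Early light-induced regulators are highest against the first set (2.83) and PIF-induced growth genes lowest (-2.10), while root and vascular markers, chlorophyll synthesis and light harvesting genes lie far apart between the dark sets.

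Against WT_dark 1-3 alone, limma called 12317 of 19985 genes (5736 higher and 6581 lower in blue light, 4656 of them at least 2-fold, median of all genes -0.04). Against WT_dark 4-6 alone it called 5794 (1805 higher and 3989 lower) and against all 6 it called 6852. Of the genes called against WT_dark 1-3, 63.8% also differed between the dark sets. Large changes of this kind were not seen against the second set: the helicase gene emb1507 (-5.40 against -0.10) and the myrosinase-like genes BGLU34 and BGLU35 (-4.18 and -4.14 against 0.03 and 0.04). With rRNA and organelle loci left out, the median of all genes moved from -0.04 to -0.15.

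In cry2, the same genes were higher after blue light: BBX32 (6.94 ± 0.15, adjusted p = 5.73e-12), PRR9 (5.70), SIG5 (4.90), ABCI21 (4.02) and HY5 (2.67 ± 0.08, adjusted p = 1.88e-10), the bZIP gene that promotes seedling greening. PAP1, a regulator of anthocyanin synthesis, increased by 2.71. PIL1 (-3.12), IAA29 (-3.64), IAA19 (-2.85) and EXPA8 (-2.51) fell. Early light-induced regulators (24 rose and 1 fell of 26, median 2.71, adjusted p = 4.29e-16), clock genes (26 of 28 rose, median 2.26, adjusted p = 4.29e-16) and expansins (16 of 23 fell, 17 adjusted over the list alone, median -1.19, adjusted p = 3.25e-06) moved as sets, also with an estimated correlation (adjusted p = 0.0185, 0.0193 and 0.0185). Light harvesting genes rose (18 of 22, median 0.81, adjusted p = 9.50e-07, adjusted p = 0.3116 with an estimated correlation). In total 11180 genes were called (5149 higher and 6031 lower, 3641 at least 2-fold). No dark library of either genotype belongs to the M series, so light and library series cannot be told apart in cry2 or in wild type. Wild type could be compared with dark libraries of the Da and D series, and cry2 with those of Db only.

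To assess whether the light response differed between cry2-1 and wild type, the blue-minus-dark change in cry2 was tested against that in wild type. PAL2 (AT3G53260), a phenylalanine ammonia-lyase gene, showed the clearest difference (3.22 ± 0.20, adjusted p = 3.41e-06): it went from 44.5 ± 3.15 to 24.3 ± 3.05 TPM (SD, n = 3) in wild type and from 15.1 ± 1.41 to 82.9 ± 15.6 TPM in cry2. PAP1 responded more in cry2 (1.77 ± 0.31, adjusted p = 0.0184), a call lost without WT_dark 1 (1.65) or cry2_dark 3 (1.68). The bZIP gene HYH (-1.33 ± 0.20, adjusted p = 0.0084), the photosystem I gene PSAK (-1.44 ± 0.19, adjusted p = 0.0059) and the root ferredoxin reductase gene RFNR2 (-1.10) responded less. The abscisic acid marker RAB18 (2.84 ± 0.47, adjusted p = 0.0144), the sugar starvation gene DIN2 (2.08), the nitrilase gene NIT2 (1.81) and SLAH1 (1.69), an anion channel gene, responded more in cry2. SNOR111, a small nucleolar RNA locus, was listed at 0 in both dark sets, in cry2_dark and in cry2_blue, and at 30.4 ± 9.60 TPM in WT_blue. In the fl4 comparison without fl4_dark 3 it was at 1.98 ± 1.13 (SE, not called), so it was also listed in dark fl4. Its presence was therefore not limited to blue light.

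With WT_dark 1-3 as the dark control, light harvesting and Rubisco genes responded less in cry2 (0 higher and 8 lower of 22, 11 lower adjusted over the list alone, median -0.60, adjusted p = 3.32e-08), and sugar starvation genes responded more (2 higher, 6 adjusted over the list alone, median 0.46, adjusted p = 3.47e-05). Abscisic acid genes were also higher (2, or 7 higher and 1 lower adjusted over the list alone, median 0.51, adjusted p = 0.0052). No call held with an estimated correlation (adjusted p = 0.4120 for these 3 lists). With WT_dark 4-6 light harvesting genes turned to a higher response (adjusted p = 0.0492), and sugar starvation and abscisic acid genes did not pass (adjusted p = 0.7662 and 0.9667). The test called 561 genes (260 higher and 301 lower, 235 at least 2-fold), but 326, 270, 145, 95, 266, 248, 1555, 131, 109 and 213 without cry2_blue 1, cry2_blue 2, cry2_dark 1, cry2_dark 3, WT_blue 1, 2 and 3 and WT_dark 1, 2 and 3. The balance of directions depended on the scale. With rRNA and organelle loci left out the test gave 407 higher and 126 lower, and with each library scaled to its median gene 418 and 251. With WT_dark 4-6 as the dark wild type it called 4472, with 107 of the 561 among them, and with all 6 it called 4; PAL2 (1.95), PAP1 (2.96) and RFNR2 (-0.73) kept their call against WT_dark 4-6, while HYH (1.11), PSAK (0.46), SLAH1 (-0.47) and NIT2 (-1.15) changed sign, and the values of RAB18 (0.02) and DIN2 (0.23) were near 0. Among 2156 light-induced genes the median difference was -0.13 (-0.22 without WT_blue 3), and among 1885 light-repressed genes it was 0.21, with 1301 above and 584 below 0; with WT_dark 4-6 the medians were 0.56 and -0.81.

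In darkness, single genes of DNA replication, wall loosening and the clock differed between cry2 and wild-type seedlings. Genes of DNA replication such as MCM2, PCNA1 and the histone gene HTR2 were higher, as were the expansin genes EXPA1 and EXPA5, while the evening clock genes TOC1, LUX and ELF4 were lower. CAM7, a calmodulin gene (1.45 ± 0.10 against WT_dark 1-3, adjusted p = 7.64e-06, and 1.72 against WT_dark 4-6), GSTU27, a glutathione transferase gene (1.52 and 1.16), ADS4, a desaturase gene (1.57 and 1.81), and AIR1, an auxin-induced root gene (2.07 and 2.09), were higher. The lipid transfer gene LTP3 (-1.53 and -1.22) was lower. IRT1, the iron transporter gene, was at 4.72 ± 0.53 TPM (SD, n = 3) in cry2_dark, 0.67 ± 0.25 TPM in WT_dark 1-3 and listed at 0 in WT_dark 4-6. Of 19731 genes tested against each set, 2544 were called against WT_dark 1-3 and 8051 against WT_dark 4-6. Of these, 642 were called in the same direction (473 higher and 169 lower) and 532 in opposite directions. Both comparisons share the cry2_dark libraries, which favours calls in the same direction, and no expected number was computed. Agreement against both sets is therefore weak support for a single gene.

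S phase and DNA replication genes were higher in dark cry2 (19 rose and 0 fell of 32, 24 adjusted over the list alone, median 0.52, camera adjusted p = 3.57e-09, adjusted p = 0.1576 with an estimated correlation). Against both sets 10 rose, including MCM2 (0.76 ± 0.16 and 0.53), PCNA1 (0.68 ± 0.13 and 0.59), the ribonucleotide reductase gene TSO2 (0.59 and 0.55) and HTR2 (0.75 ± 0.10 and 0.51), although reads of histone H3 copies may be shared. Against WT_dark 4-6 alone the list median was 0.21 (adjusted p = 0.1829), and MCM5 (0.88 and -0.09), MCM3 (0.86 and -0.03) and CYCA3;2 (0.83 and -0.14) changed sign. Mitotic genes were higher (5 of 34, 8 adjusted over the list alone, median 0.27, adjusted p = 0.0113, adjusted p = 0.6683 with an estimated correlation), with CDKB2;2 (0.57 and 0.99) called both ways. Its call against WT_dark 1-3 ended without any 1 of the 6 libraries (0.45 to 0.64). These groups moved with the rRNA loci, which took 12231 to 15977 TPM in cry2_dark and 56392 to 65586 TPM in WT_dark 1-3.

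Clock genes were lower in dark cry2 (0 rose and 8 fell of 28, median -0.28, adjusted p = 1.37e-05, adjusted p = 0.1988 with an estimated correlation), 7 of them against both sets: PRR7 (-0.55 and -1.10), TOC1 (-0.63 and -0.60), LUX (-0.39 and -0.64), ELF4 (-0.43 and -0.58), LNK2 (-0.46 and -1.28), RVE4 (-0.28 and -0.81) and RVE7 (-0.47 and -1.33). Single libraries decided several of these calls against WT_dark 1-3. That of ELF4 ended without any 1 of the 6 libraries (-0.33 to -0.49), that of LUX without WT_dark 1, 2 or 3 or cry2_dark 1 or 3 (-0.30 to -0.41), and those of PRR7 (-0.43 to -0.54) and RVE7 (-0.32 to -0.49) without WT_dark 2 or 3 or cry2_dark 1 or 3. Expansins and xyloglucan enzymes were higher in 6 of 23 (8 higher and 1 lower adjusted over the list alone, median 0.26), but the list did not pass (adjusted p = 0.0667), and 5 rose against both sets. EXPA1 changed by 0.81 and 1.28 (0.74 and no longer called without cry2_dark 1), EXPA5 by 0.58 and 0.78 and XTH18 by 0.76 and 0.83. PIF4, a growth-promoting factor gene, was lower (-0.53 and -0.69; -0.44 and not called without WT_dark 2), as was HY5 (-0.41 ± 0.08 and -1.25).

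Several lists that moved against WT_dark 1-3 did not move the same way against WT_dark 4-6. Abscisic acid genes were lower (0 rose and 6 fell of 12, 7 adjusted over the list alone, median -0.50, adjusted p = 7.70e-07, adjusted p = 0.0366 with an estimated correlation), with RAB18 at -2.01 ± 0.33 (adjusted p = 0.0031) and 0.81 against the second set, where the list did not pass (adjusted p = 0.5383). Sugar starvation genes (0 rose and 6 fell of 18, 12 adjusted over the list alone, median -0.39, adjusted p = 5.41e-09, adjusted p = 0.1781 with an estimated correlation) did not pass there either (adjusted p = 0.8466). Light harvesting genes were higher (11 of 22, 14 adjusted over the list alone, median 0.49, adjusted p = 1.81e-07, adjusted p = 0.3701 with an estimated correlation) and lower against WT_dark 4-6 (median -0.48, adjusted p = 0.0066). Chlorophyll synthesis genes were higher against WT_dark 1-3 (8 of 15 rose, 9 adjusted over the list alone, median 0.55, adjusted p = 2.05e-05, adjusted p = 0.4933 with an estimated correlation) but not against WT_dark 4-6 (median -0.29, adjusted p = 0.0730). The photoreceptor list passed with 2 genes lower (adjusted p = 0.0072, adjusted p = 0.6683 with an estimated correlation). EARLI1, a lipid transfer-like gene, was at 172 ± 20.9 TPM in cry2_dark, 30.0 ± 7.74 TPM in WT_dark 1-3 and 232 ± 43.0 TPM in WT_dark 4-6 (SD, n = 3), so its change turned with the control.

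Against WT_dark 1-3, 2578 of 19985 genes were called in cry2_dark (2001 higher and 577 lower, 393 at least 2-fold), against all 6 dark wild-type libraries 414 and against WT_dark 4-6 8104. The count was 1451, 1103, 1327 and 1039 without cry2_dark 1, cry2_dark 3, WT_dark 1 and WT_dark 2. The median of all genes was 0.10, and with each library scaled to its median gene it was 0.01 (1147 higher and 1038 lower). Header names begin with Da for WT_dark 1-3 and with Db for cry2_dark, so genotype and header prefix cannot be told apart in this comparison.

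In blue light, where both genotypes belong to the M series, cry2 had higher levels of single genes of the cell cycle, of phenylalanine and anthocyanin metabolism and of phosphate use. PAL2 (1.72 ± 0.14, adjusted p = 7.88e-05), the anthocyanin genes PAP1 (1.74 ± 0.22, adjusted p = 0.0026) and GSTF12 (1.88 ± 0.23, adjusted p = 0.0023) and the flavonol regulator MYB11 (1.32, adjusted p = 0.0109) were higher. AIR1 rose from 15.1 ± 4.98 to 108 ± 30.7 TPM (2.78 ± 0.26, adjusted p = 9.68e-04), and the phosphatase gene PS2 (2.61 ± 0.33) and the galactolipid synthase gene MGD2 (1.36 ± 0.17) were higher at adjusted p = 0.0025. LTP3 (-2.01 ± 0.23, adjusted p = 0.0025), the triterpene pathway gene CYP705A5 (-1.33), the pectin methylesterase gene ATPMEPCRD (-1.13) and the flowering repressor FLC (-1.07 ± 0.17, adjusted p = 0.0074) were lower.

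S phase genes were higher in cry2 in blue light (7 of 32, 18 adjusted over the list alone, median 0.35, adjusted p = 1.05e-07), as were mitotic genes (4 of 34, 14 adjusted over the list alone, median 0.37, adjusted p = 4.61e-07) and flavonoid genes (3 of 10, 6 adjusted over the list alone, median 1.01, adjusted p = 4.30e-05). Touch genes were lower (1 of 20, 4 adjusted over the list alone, median -0.36, adjusted p = 7.46e-08), with CBF3 at -0.87 (-0.79 and not called without cry2_blue 1). The lower touch mean came from cry2_blue 1 and 2 (4.66 and 4.61), while cry2_blue 3 (5.53) lay above WT_blue (5.30 to 5.37). No list held with an estimated correlation (adjusted p = 0.3312 for these 4). PCNA2 (0.46, adjusted p = 0.0151) and CYCB2;3 (0.70, adjusted p = 0.0108) kept their call with any 1 library left out of the fit of 12, but not in a fit of the 6 blue-light libraries. Without cry2_blue 2 the calls of MCM2 (0.86, then 0.77), MCM3 (0.68, then 0.61), CDC20.1 (0.62, then 0.59) and the CDK inhibitor gene SIM (-0.59, then -0.53) ended. Vascular markers were higher (2 of 15, 7 adjusted over the list alone, median 0.43, adjusted p = 7.71e-04, adjusted p = 0.4194 with an estimated correlation), including TMO5 (0.70, adjusted p = 0.0080). EXPA15 increased by 0.68 (adjusted p = 0.0108).

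In total 668 genes were called in blue light (521 higher and 147 lower, 204 at least 2-fold, median of all genes 0.11), 269 without cry2_blue 2, 355 without WT_blue 2 and 14 when the fit held only these 6 libraries. Of the genes named here as called in blue light, PAL2, AIR1 and LTP3 kept their call in that fit and the others did not. The effects of cry2 in darkness and blue light shared more calls in the same direction than random overlap gives. In both, 163 genes were higher (52.2 expected by chance, Fisher's exact test, 2-sided, p = 2.75e-42) and 30 lower (4.24 expected, Fisher's exact p = 2.18e-17), while 14.7 were expected and 2 found higher in darkness and lower in blue light. Lower in darkness and higher in blue light were 12 genes (15.04 expected, Fisher's exact p = 0.5072). Genes are not independent, and both effects come from 1 fit with the same error per gene, which favours calls in both. The median of all genes was also above 0 in each (0.10 in darkness and 0.11 in blue light). Random overlap is therefore not a full baseline, and these p-values are descriptive.

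In dark fl4 seedlings few genes were called against WT_dark 4-6, and they included single phosphate-starvation and stress genes. In simulated data this comparison recovered 34.0% of 2-fold changes, so few calls do not mean few differences. MIR827, the locus of a phosphate-starvation microRNA, was listed at 0 in all 6 dark wild-type libraries and at 10.4 ± 3.19 TPM (SD, n = 3) in fl4_dark. QQS, a starch-regulating orphan gene, was at 117 ± 29.9 TPM against 5.98 ± 3.18 TPM (4.14 ± 0.32, adjusted p = 0.0067). ALS3, an aluminium tolerance gene (1.68 ± 0.17, adjusted p = 0.0074), and HOL2, a methyltransferase gene (2.11 ± 0.21, adjusted p = 0.0074), were higher. These 4 genes kept their call with any 1 library left out and were also higher against WT_dark 1-3 (QQS 6.27, ALS3 0.85, HOL2 1.24). MYB10 was higher (1.48 ± 0.17, adjusted p = 0.0144; 1.45 and 1.44 and not called without fl4_dark 1 and WT_dark 6).

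The phosphate-starvation RNA AT4 (1.74 ± 0.24, adjusted p = 0.0426) and the glycerol-phosphate permease gene G3Pp1 (0.91 ± 0.13, adjusted p = 0.0450) were higher. Without fl4_dark 1, fl4_dark 2, WT_dark 5 or WT_dark 6 the calls of several further genes ended. They were the dehydration marker RD29B (1.88, and 1.62 to 1.99 in those fits), SIS (1.13, and 1.03 to 1.22), the plasmodesmal callose-binding gene PDCB5 (-1.64, and -1.49 to -1.76), the germin-like gene GER2 (-1.92, and -1.91 without WT_dark 6), the crossover gene HEI10 (-1.42, and -1.44 to -1.50) and UPP (-1.36, and -1.15 to -1.45). EARLI1 was lower (-1.79 ± 0.19, adjusted p = 0.0113; -1.81 and not called without fl4_dark 1) but higher against WT_dark 1-3 (1.13).

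No member of the S phase list was called in fl4 over all genes (26 of 32 were lower adjusted over the list alone, median -0.77, camera adjusted p = 4.19e-11, adjusted p = 0.6480 with an estimated correlation). HTR2 was at -0.98 (adjusted p = 0.0620) and CYCA3;2 at -1.12 (adjusted p = 0.0724). Without fl4_dark 3, limma called 25 of the 32 lower (median -0.91). The mean log2 value of the list was 3.65, 3.87 and 3.68 in WT_dark 4-6, 2.83, 2.81 and 3.36 in fl4_dark 1-3 and 3.36, 3.26 and 3.47 in WT_dark 1-3. The libraries with the lowest values, fl4_dark 1 and 2, also held the most rRNA of the 3 (31348 and 15784 TPM). Mitotic genes were lower as a set with none called (of 34, median -0.47, adjusted p = 2.73e-04, adjusted p = 0.6991 with an estimated correlation), and 13 were called lower without fl4_dark 3. Other sets with a lower test result were auxin transport (5 adjusted over the list alone, median -0.57, adjusted p = 0.0051, adjusted p = 0.6991 with an estimated correlation) and shoot apex markers (5 of 10 adjusted over the list alone, median -0.99, adjusted p = 0.0111, adjusted p = 0.6480 with an estimated correlation).

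Expansins (1 of 23 adjusted over the list alone, median -0.46, adjusted p = 0.0115, adjusted p = 0.6480 with an estimated correlation) and chlorophyll synthesis genes (4 of 15 adjusted over the list alone, median -0.54, adjusted p = 0.0135, adjusted p = 0.7476 with an estimated correlation) also passed downwards with no gene called over all genes. The first call ended without fl4_dark 3 (adjusted p = 0.0888) and the second without fl4_dark 1, fl4_dark 3, WT_dark 5 or WT_dark 6 (adjusted p = 0.0716, 0.2169, 0.0578 and 0.0531). The clock list passed upwards (median 0.04, adjusted p = 0.0292, adjusted p = 0.7840 with an estimated correlation), a call that ended without fl4_dark 3, WT_dark 4 or WT_dark 5 (adjusted p = 0.3505, 0.3966 and 0.0559).

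Sugar starvation (median 0.19, adjusted p = 0.0032, adjusted p = 0.4460 with an estimated correlation), abscisic acid (1 of 11 rose, median 0.36, adjusted p = 0.0051, adjusted p = 0.5430 with an estimated correlation) and ethylene response genes (median 0.26, adjusted p = 0.0051, adjusted p = 0.6480 with an estimated correlation) passed upwards. Vascular markers did not pass (median -0.47, adjusted p = 0.2436), nor did the 3 seed reserve genes (median 0.48, adjusted p = 0.1755). In all, limma called 59 of 19411 genes in fl4_dark (43 higher and 16 lower, 51 at least 2-fold) and 4044 had an unadjusted p under 0.05. Against all 6 dark wild-type libraries it called 247, and against WT_dark 1-3 it called 9790, of which 46 matched the direction of the first call. The count was 19, 27, 2940, 331, 26 and 21 without fl4_dark 1, 2 and 3 and WT_dark 4, 5 and 6. That WT_dark 4-6 are the controls of fl4 was read from the numbering of the titles and from the header names, not from a statement.

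**Figure D4:**
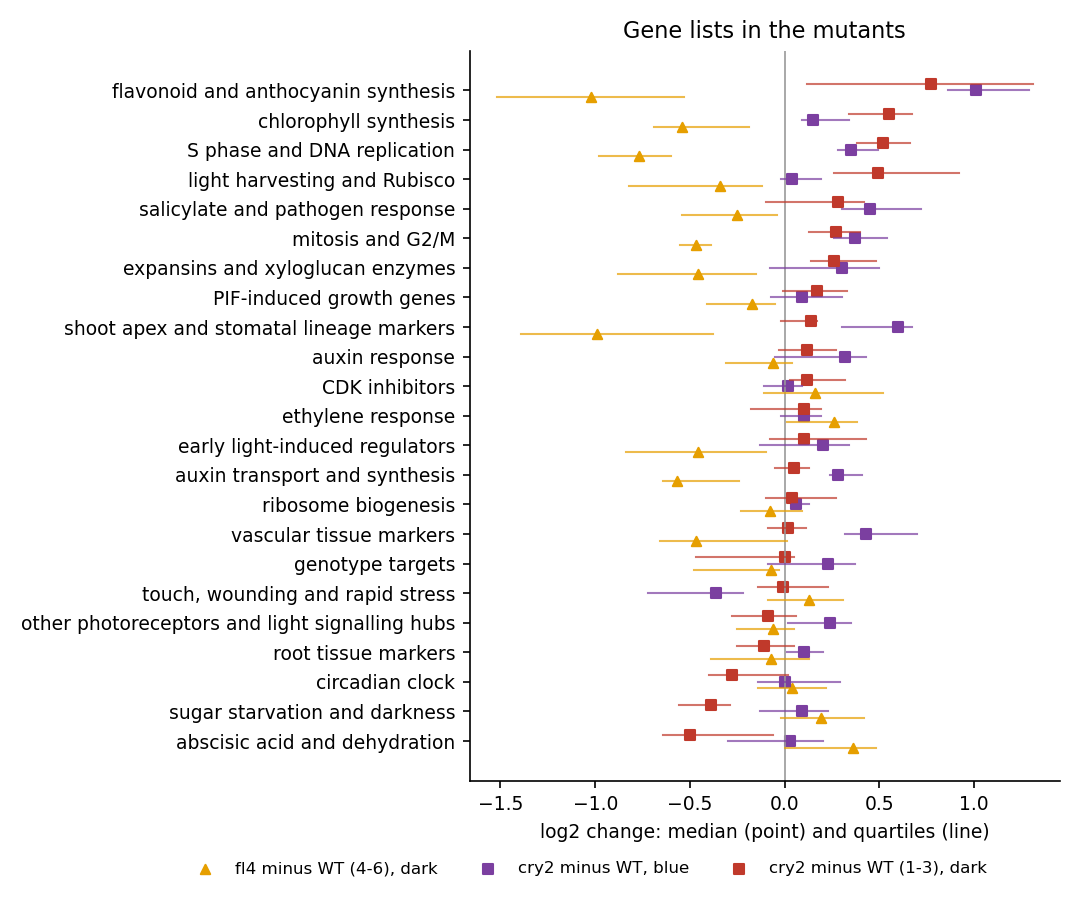
Median log2 change of each gene list in cry2 in darkness (against WT_dark 1-3), cry2 in blue light and fl4 in darkness (against WT_dark 4-6), with lines from the lower to the upper quartile of the list members. The S phase list is above 0 in cry2 (0.52 and 0.35) and below 0 in fl4 (-0.77).

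**Figure D5:**
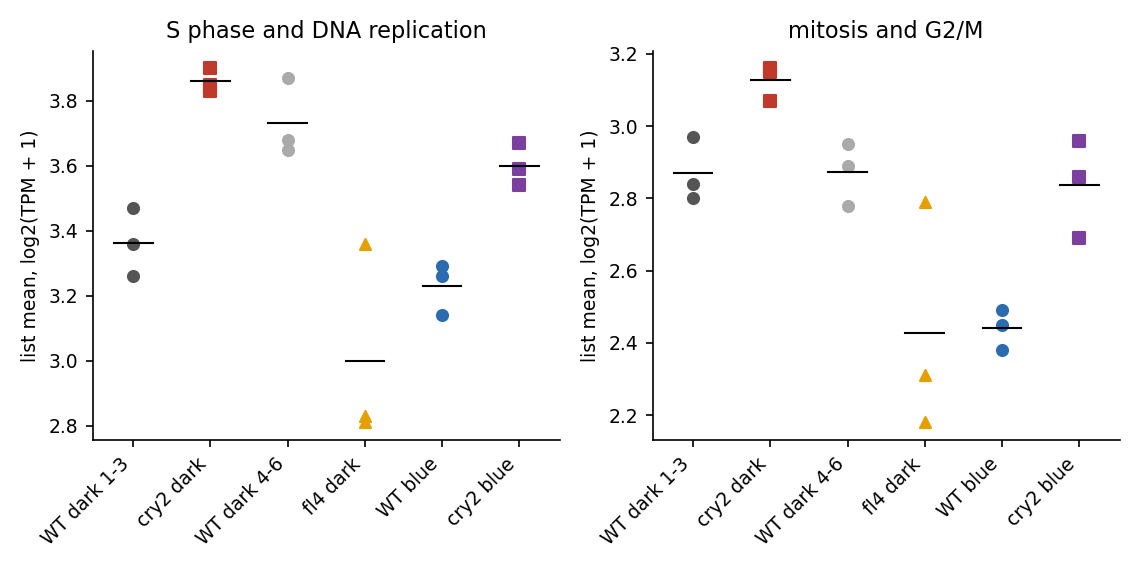
Mean log2(TPM + 1) of the S phase and the mitotic genes, with 1 point per library and lines at the mean of each set. S phase means are 3.83 to 3.90 in cry2_dark, 3.26 to 3.47 in WT_dark 1-3, 3.65 to 3.87 in WT_dark 4-6 and 2.81 to 3.36 in fl4_dark.

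To compare the mutants, calls in darkness were matched over 19082 genes. Those higher in both were G3Pp1, AT4, the sucrose synthesis gene ATSPS4F and the sulfate transporter-like gene SULTR3;5 (4 genes, as many as chance gives, Fisher's exact p = 1.0000), and none was lower in both. EARLI1, HEI10 and UPP were among 7 genes higher in cry2 and lower in fl4 (1.64 expected, Fisher's exact p = 5.83e-04), and RD29B was among 4 genes lower in cry2 and higher in fl4 (1.13 expected, Fisher's exact p = 0.0260). Across genes, which are not independent, the changes were correlated at r = -0.223 (Spearman's rho -0.302). The opposite calls numbered 3, 5, 431, 108, 3 and 2 without fl4_dark 1, 2 and 3 and WT_dark 4, 5 and 6, and 6 and 7 without WT_dark 2 and cry2_dark 3, and the same-direction calls ran from 0 without WT_dark 5 to 49 without fl4_dark 3. Exchanging the dark controls gave 6400 opposite and 20 same-direction calls.

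The 2 sets of dark wild-type libraries differed in many genes, among them markers of tissues and light-related genes. In WT_dark 4-6, root markers were lower than in WT_dark 1-3 (8 of 11, median -1.67, adjusted p = 3.16e-04, adjusted p = 0.4205 with an estimated correlation), including the proline-rich gene PRP3 (-2.60), the auxin carrier gene PIN2 (-1.70) and the phosphate transporter gene PHT1;1 (-1.68). Vascular markers were lower too (11 of 15, median -0.88, adjusted p = 2.79e-04, adjusted p = 0.4205 with an estimated correlation), including the xylem genes XCP1 (-2.92), XCP2 (-2.61) and CESA7 (-2.17). Light harvesting genes (16 higher and 1 lower of 22, 17 higher adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.6087 with an estimated correlation) and HYH (2.44) were higher. LHCB1.5 was listed at 0 in WT_dark 4-6 and at 1490 ± 268 TPM in WT_dark 1-3. The helicase gene emb1507 was at 42.8 ± 4.44 TPM in WT_dark 1-3 and 0.11 ± 0.05 TPM in WT_dark 4-6, and PHYE at 4.43 ± 0.64 and 53.9 ± 7.18 TPM. In total 10015 of 19703 genes were called (5864 higher and 4151 lower in WT_dark 4-6, 2802 at least 2-fold). The balance of directions depended on the scale. With rRNA and organelle loci left out 4737 were higher and 5421 lower, and with each library scaled to its median gene 5215 and 4990. Nothing in the labels says that replicates came from separate cultures, so all p-values may measure technical spread only.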

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

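The interaction, the fl4 comparison, the gene lists and the use of all 6 dark libraries were planned, as were the tests of overlapping genes, of ribosomal RNA within library sets and of exchanged labels, while the other tests of explanations, the fit of the difference between the mutant effects in all 18 libraries and WT_dark 4-6 in the interaction were chosen only after the result was seen. The light response differed between wild type and cry2 in 561 genes. The differences (cry2 minus wild type, log2) were 3.22 for PAL2, 1.69 for SLAH1, 2.14 for the wall protein gene HRGP1, 1.81 for NIT2, 1.17 for GLYI7, 2.08 for DIN2, 1.77 for PAP1, 2.84 for RAB18, 0.57 for the phosphatase gene ABI1, 1.89 for PRP3, 0.78 for PHT1;1, 0.72 for the root patterning gene SHR and 0.98 for the xylem gene ACL5. Among clock genes they were 0.95 for LNK2 and 0.83 for PRR7, and MCCB was at 0.54. Lower in cry2 were PSAK (-1.44), EARLI1 (-1.67), WRKY60 (-1.04), HYH (-1.33), RFNR2 (-1.10), HTR2 (-0.61), ELIP1 (-1.26), LHCB6 (-1.01), LHCB1.1 (-2.04), LHCA1 (-0.88), RBCS1B (-0.99), XTH18 (-0.88) and IRT1 (-1.62, with WT_blue listed at 0). Only PAL2, SLAH1, HRGP1, NIT2, GLYI7, DIN2, RAB18, PSAK, EARLI1, WRKY60, HYH, RFNR2 and IRT1 kept their call with any 1 library left out. With WT_dark 4-6 as control, SLAH1 (-0.47), NIT2 (-1.15), PSAK (0.46), EARLI1 (1.25), HYH (1.11), ELIP1 (1.05), LHCB6 (0.19), LHCB1.1 (1.58), LHCA1 (0.79), RBCS1B (0.95), PHT1;1 (-0.90), SHR (-0.04) and ABI1 (-0.02) changed sign, and RAB18 was at 0.02.

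With WT_dark 1-3 as control, list medians of this difference were 0.28 for photoreceptors and light signalling hubs, -0.60 for light harvesting and Rubisco, -0.38 for chlorophyll synthesis, 0.15 for the clock, -0.55 for touch genes, 0.46 for sugar starvation, 0.51 for abscisic acid genes and 0.53 for vascular markers, and none of these lists passed with an estimated correlation. With WT_dark 4-6 the direction turned for light harvesting and chlorophyll synthesis (adjusted p = 0.0492 for each) and vascular markers (adjusted p = 0.0199), and sugar starvation, abscisic acid and photoreceptor lists did not pass (adjusted p = 0.7662, 0.9667 and 0.1555). Without WT_blue 3 the photoreceptor call ended (adjusted p = 0.0951), and without WT_blue 3, cry2_blue 1 or cry2_blue 2 the touch call ended (adjusted p = 0.0674, 0.1052 and 0.1660). With WT_dark 1-3 as control the median difference of light-repressed genes was 0.21, a smaller change in cry2, but it turned to -0.33 with all 6 dark libraries and -0.81 with WT_dark 4-6. When genotype labels were exchanged within each light condition, 2 of 100 splits drawn from 200 called as many genes, the real one included (561 against 1251 for the highest other). That split set WT_dark 1-3 with cry2_blue 1, cry2_blue 2 and WT_blue 1 as the mutant arm, so it follows structure among the libraries. The alternative dark controls weigh more than these splits, because 4 and 4472 genes were called with all 6 and with WT_dark 4-6.

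The effects of the mutants in darkness, compared in a fit of all 18 libraries, differed in 4399 of 19927 genes (1061 higher and 3338 lower in fl4 than in cry2). That fit pools the error over all groups. For fl4 alone it called 2770 genes, against 59 in the fit of 6 libraries, so 4399 may be too high. The cry2 effect within it cannot be told apart from the header prefix, and the controls of each mutant were read from the titles. Exchanging the labels within each dark set gave as many calls in 1 of 100 splits, the real one (highest other 2600). That other split kept all cry2_dark libraries in the mutant arm and exchanged only fl4_dark 3 with WT_dark 4. List medians of the difference were -0.75 for mitosis, -1.37 for S phase, -1.10 for light harvesting, -1.07 for chlorophyll synthesis, -0.81 for expansins, 0.26 for the clock, 0.59 for sugar starvation, 0.85 for abscisic acid genes and 0.04 for ethylene response. With an estimated correlation the abscisic acid list still passed (adjusted p = 0.0264), and the others did not (adjusted p = 0.0940 for sugar starvation, 0.3436 for S phase, 0.6141 for light harvesting and 0.5540 for the other 5).

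For the comparisons of 3 libraries with 3 only 10 splits exist, too few for a share under 0.05, and in each of them 1 split, the real one, called as many genes as were found. The real and the highest other counts were 12317 and 1 for light in wild type, 11180 and 1 for light in cry2, 2578 and 2 for cry2 in darkness, 668 and 10 for cry2 in blue light, 59 and 5 for fl4, and 10015 and 1 for the dark wild-type sets. Within the 6 dark wild-type libraries, 33 measures (RNA shares, genes detected, list means and targeted genes) were examined with Dixon's test for a single extreme library, and 0 passed the limit, with 1.65 expected by chance. Such a test does not see a split into 2 sets of 3.

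The difference between WT_dark 1-3 and WT_dark 4-6 was weighed against 3 explanations. If reads of overlapping genes had been assigned differently, genes with no overlapping gene would seldom be called, but 50.9% of 12893 such genes were called, which excludes this as the whole cause. With rRNA and organelle loci left out and each library scaled to its median gene, 10125 genes were called. A shift of all other genes alike by the share of these RNAs is therefore excluded as the whole cause. The test does not see uneven changes of other genes that go with these RNAs. If WT_dark 4-6 held less root tissue, abundant root genes would all fall, but the root gene PYK10 changed by 0.06 while the root marker median was -1.67 (difference 1.74 ± 0.35, SE), though PYK10 is not confined to roots. Growth, harvest, library preparation and read assignment other than at overlapping genes were not tested. Since the sets share genotype and condition, any of these may be the cause.

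The S phase list was higher in cry2 (adjusted p = 0.1576 with an estimated correlation, 0.1829 against WT_dark 4-6) and lower in fl4 (adjusted p = 0.6480 with an estimated correlation, with no gene called), so the pattern itself is weak. Within the 6 sets of libraries the S phase mean fell as rRNA rose (r = -0.71, permutation p = 0.1133, 18 libraries, 1 relation tested; -0.43 without fl4_dark 1 and fl4_dark 3), which leaves rRNA open as a cause in darkness. In blue light cry2_blue had higher S phase means than WT_blue (3.54 to 3.67 against 3.14 to 3.29). Their log2 rRNA values overlapped (12.84 to 13.28 against 13.01 to 13.73), so this does not decide it. Fl4_dark held less summed rRNA than WT_dark 1-3 yet had S phase means of 2.81 to 3.36 against 3.26 to 3.47, the reverse of this relation. Compared with WT_dark 4-6, fl4_dark held more rRNA (log2 13.52 to 14.94 against 12.68 to 12.95) and had lower S phase means, as the relation gives. A uniform shift of the scale moves all genes alike, so it does not account for a list median 0.42 above that of all genes in cry2 and at -0.65 from it in fl4, distances that scaling the libraries leaves unchanged by construction. More dividing tissue in cry2 and less in fl4 would move mitotic genes as far as S phase genes, and the ratios of the medians were 0.51 and 0.62, which leaves this open to a test such as flow cytometry of nuclei.

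The small number of genes called in fl4 depended on single libraries, as 2940 genes were called without fl4_dark 3, 331 without WT_dark 4 and 59 with all 6. The root mean square distance (log2) of a library from the mean of the other libraries of its group was 0.591 for fl4_dark 3, 0.510 and 0.503 for fl4_dark 1 and 2, and 0.375 to 0.449 for WT_dark 4-6. On the third principal component fl4_dark 3 (-21.42) lay nearer to WT_dark 4-6 (-44.90 to -21.37) than to fl4_dark 1 and 2 (35.33 and 15.36). LHCB1.5 was higher in fl4 by 9.42 ± 0.21 (SE, adjusted p = 4.47e-05) without fl4_dark 3, but was not called with all 6 libraries. The fl4 libraries thus differ in more than random spread, and the cause was not tested. No label gives a reason to leave fl4_dark 3 or WT_dark 4 out. A further set of fl4 and wild-type libraries grown together would show which count holds.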

How the results depend on the processing

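The tests in this part that scaled libraries, left out rRNA or overlapping genes, asked for 5 TPM in 3 libraries, or used WT_dark 4-6 in the interaction and for the light-response size were chosen only after the result was seen. Apart from the dark control used, most choices left the counts within 1.5-fold. The cause of each difference was not tested unless stated.

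With a 2-fold minimum, which by construction lowers counts, the calls were 4656 for light in wild type, 3641 for light in cry2, 235 for the interaction, 393 for cry2 in darkness, 204 for cry2 in blue light and 2802 between the dark sets. Light in wild type gave 6852 calls against all 6 dark libraries and 5794 against WT_dark 4-6. The interaction gave 4 and 4472 in the same order. Cry2 in darkness gave 414 and 8104, and 4568 when only the groups compared were fitted, while cry2 in blue light gave 14 in a fit of its own groups. Such a fit has fewer residual degrees of freedom by construction, but the counts in darkness and in blue light moved in opposite directions. The fit of 12 libraries pools the error of the dark and blue-light groups. Distances from the rest of the group were 0.358 to 0.423 in WT_dark 1-3 and cry2_dark. They were 0.392 to 0.414 in the blue-light groups except WT_blue 3 (0.565). The cause was not tested.

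For fl4 the calls were 14 with no filter, 111 with at least 5 TPM in 3 libraries, 247 against all 6 dark wild-type libraries, 9790 against WT_dark 1-3 and 2770 with all 18 libraries in 1 fit. Against WT_dark 1-3 with the replicate number as a block they were 9872. With that block, the fit of 12 libraries called 12264 genes for light in wild type, 11076 for light in cry2, 391 for the interaction, 2275 for cry2 in darkness and 603 for cry2 in blue light. Residual correlations between libraries of the same number ran from -0.06 to 0.23, so the numbers do not mark shared batches throughout.

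Leaving out each library in turn gave 11190 to 12512 calls for light in wild type, 9706 to 10404 for light in cry2, 95 to 1555 for the interaction, 1039 to 1838 for cry2 in darkness, 269 to 790 for cry2 in blue light, 19 to 2940 for fl4 and 7938 to 10342 between the dark sets. Between 72 and 79 list results passed, against 74 with all libraries. Comparisons that did not compare the library left out kept their main count, which narrows this range. In the interaction 7 to 12 lists passed, against 8, and for fl4 8 to 13, against 10. With an estimated correlation 7 list results remained.

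The overlap of the mutants in darkness, 4 calls in the same and 11 in opposite directions (r = -0.223), became 3 and 44 (r = -0.486) with all 6 dark libraries for both mutants, 20 and 6400 (r = -0.818) with the dark sets exchanged, 1 and 5 with a 2-fold minimum and 2 and 6 with libraries scaled to the median gene. Leaving out each library gave 0 to 49 and 2 to 431, with r from -0.230 to -0.189. With all 6 or exchanged controls, the difference between the dark sets enters the mutant effects with opposite sign by construction.

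The median difference of light-repressed genes, 0.21, was 0.11 with no fold minimum, 0.15 to 0.24 with each library left out, -0.33 with all 6 dark libraries and -0.81 with WT_dark 4-6. For light-induced genes it was -0.13, and -0.22 without WT_blue 3 (-0.22 to -0.08 over all libraries), 0.33 with all 6 dark libraries and 0.56 with WT_dark 4-6. This result therefore may rest on the dark control used.

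Changes in direction came only from the dark control. For light in wild type, WT_dark 4-6 gave BGLU35 0.04, BGLU34 0.03, PHYE -0.03, CDC20.1 -0.42, WRKY70 0.38, SID2 -0.05, GRX480 0.25 and CESA7 0.26. In the interaction all 6 gave PHT1;1 -0.06. There WT_dark 4-6 gave SLAH1 -0.47, NIT2 -1.15, PSAK 0.46, EARLI1 1.25, HYH 1.11, ELIP1 1.05, LHCB6 0.19, LHCB1.1 1.58, LHCA1 0.79, RBCS1B 0.95, GH3.5 -0.51, ABI1 -0.02, PHT1;1 -0.90 and SHR -0.04.

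For cry2 in darkness all 6 dark libraries gave CDC20.1 -0.16, RBCS3B -0.01 and GH3.5 0.09. Against WT_dark 4-6 the values were FL1 0.60, FL3 0.43, EARLI1 -0.42, CA1 -0.51, SLAH1 0.64, 3xHMG-box2 -0.27, CDC20.1 -0.80, MCM5 -0.09, MCM3 -0.03, CYCA3;2 -0.14, HYH -1.14, ELIP1 -0.88, ELIP2 -0.60, F3H -0.43, RBCS3B -0.87, LHCB6 -0.22, RBCS1B -0.73, LHCB3 -0.46, PORC -0.29, CHLI1 -0.07, DVR -0.09, CRD1 -0.17, GH3.5 0.60, LAX1 0.07, XTH5 -0.06, ERF104 0.27, SID2 -0.43, DIN2 0.76, TPS9 0.37, RAB18 0.81, HAI1 0.13, ABI1 0.15, NCED3 0.42, NOP56 -0.03, PIP2;4 0.42 and ACL5 0.53. For fl4, WT_dark 1-3 gave FL3 -0.79 and EARLI1 1.13, with and without the block.

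Count-based normalization, a second count-based tool and filters on counts or CPM were planned and not run, as the values are TPM.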

Other observations

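All tests in this part were chosen only after the result was seen. Several genes of suberin, the lipid barrier of root endodermis and outer tissues, were higher in cry2 in darkness and in blue light. CYP86A1, a fatty acid hydroxylase gene, increased by 1.76 and 1.27 (log2, darkness and blue light), CYP86B1 by 1.60 and 1.23, the transporter gene ABCG6 by 1.27 and 1.62, the acyltransferase gene GPAT5 by 1.14 and 1.04, MYB93 by 1.06 and 1.53 and the feruloyl transferase gene ASFT by 0.69 and 0.79. Of 17 genes 9 rose in darkness (median 0.69) and 8 in blue light (median 1.03). These calls are from the fit of 12 libraries. A fit of the 6 blue-light libraries called 14 genes in all, 8 of them higher, so most such calls depend on the larger fit. Against WT_dark 4-6, 7 rose (median 0.39). The list did not pass with an estimated correlation (camera p = 0.1881 in darkness, 0.0670 in blue light and 0.3016 against WT_dark 4-6).

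Genes of the phosphate-starvation response were higher in cry2 too. SPX1, a phosphate sensor gene, increased by 1.41 and 1.80, the RNA AT4 by 1.86 and 1.95, its relative IPS1 by 1.27 and 1.76, the sulfolipid gene SQD1 by 0.98 and 1.33 and the transporter gene PHT1;4 by 0.66 and 1.11. Of 14 genes tested 8 rose in darkness (median 0.64) and 9 in blue light (median 1.00), and 4 rose against WT_dark 4-6 (median 0.37). The blue-light calls are again from the fit of 12 libraries, while the fit of the 6 blue-light libraries called 8 genes higher in all. In fl4 the same list held 3 genes that rose, MIR827, AT4 and G3Pp1, with a median of -0.09.

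Heat-shock genes rose after blue light in wild type. HSP17.6A increased by 5.25 ± 0.47 (SE, adjusted p = 9.68e-06), HSP23.6 by 5.17, ROF2 by 4.43, DREB2A by 3.75, HSP101 by 3.40 and HSP90.1 by 2.91. Of 20 genes 19 rose against WT_dark 1-3 (median 3.23) and 19 against WT_dark 4-6, and 20 rose in cry2 (median 3.20).

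Higher suberin genes may reflect more barrier tissue in cry2 samples, while the root marker list did not rise with them (median -0.11 in darkness and 0.10 in blue light). As a set the suberin genes passed in darkness (camera p = 2.18e-04) and in blue light (p = 5.31e-08) but not with an estimated correlation (p = 0.1881 and 0.0670), so the test leaves this open. The list was drawn up after the values were seen, so these p-values are too small. Staining of suberin in dark-grown cry2 roots would test it.

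A phosphate-starvation response in cry2 may reflect altered phosphate uptake or a difference in medium between plates. The set passed in darkness (camera p = 1.10e-04) and in blue light (p = 1.54e-10), also with an estimated correlation (p = 0.0483 and 0.0048), though against WT_dark 4-6 the latter value was 0.1168. The list was drawn up after some of its genes were seen to rise, so these p-values are too small. Phosphate measured in cry2 and wild-type seedlings grown on the same plates would test it.

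Heat-shock genes may have risen because the lamp or the handling warmed the seedlings. The set passed against both dark sets (camera p = 2.02e-10 and 4.66e-27), and with an estimated correlation against WT_dark 4-6 (p = 0.0125) but not WT_dark 1-3 (p = 0.0985), so this stays open. This list too was drawn up after the values were seen, so its p-values are too small. Dark seedlings moved in the same way without light would separate warmth from blue light.

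A group of genes close together on chromosome 3 were higher in cry2 in darkness and blue light: BPM6 (0.87 and 0.99), LTPG2 (0.86 and 0.84), AT3G43740 (0.97 and 0.80), ZIFL2 (0.94 and 1.13), GSTU27 (1.52 and 0.63) and CAM7 (1.45 and 0.84). They were picked by eye and their grouping was not tested.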
